A study of Sorghum bicolor with 4 samples.

How the data were processed

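The 4 libraries were made from Trizol total RNA of sorghum leaves with the Illumina TruSeq small RNA protocol, per the labels' protocols. Each of the deposited tables pairs distinct sequences of 18 to 44 nt with raw read counts, so the values show reads already collapsed to distinct sequences. The trimming tool, filters, aligner and genome build are not given in the sources used here. Some adapter remained, since 8.68% to 13.04% of reads still held 12 nt or more of the 5' adapter. Groups were taken from the sample titles. The combination sample carries a second tag that says drought without heat, and the title was followed.

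Families were counted from the tables with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. A list of 78 mature sequences of 31 conserved or grass miRNA families and tasiARF was written from general knowledge before the data were examined. A read of 19 to 24 nt was assigned to a family when its first 18 nt equalled those of a listed sequence, so 3' length variants were summed, and a start held by more than 1 family was given to neither. Other members of a family and other 5' ends are missed, and members with the same first 18 nt are not told apart. Values are RPM, counts scaled to 1000000 reads of all kinds per library, so the adapter fragments lower them.

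The 5 comparisons were made from 1 library per condition, each as the ratio of RPM with the exact conditional-binomial (Clopper-Pearson) 95% interval. A family was called higher or lower when it had at least 100 reads over both libraries, a ratio of at least 2 or at most 0.5 and an interval that excludes 1. This compares those libraries, not the conditions, and no p-value was computed. Shares of a library have Wilson 95% intervals. The depth of 27427142 to 31541978 reads sets a floor of 3 counts, 0.0951 to 0.109 RPM. The rule for named families was fixed before the data were examined: all families called in a comparison, and 23 miRNA families of interest plus tasiARF where they had 100 reads. miR530, with miR1432 outside a call, was named after its values were seen. For 9 family lists, fixed beforehand, the median log2 ratio was set among 10000 random lists of the same size and expression tercile, as a description of these libraries.

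Alternatives fixed beforehand were reads of 20 to 24 nt or of the listed miRNA families as the denominator, median-of-ratios size factors, TMM factors from edgeR 4.0.16 in R 4.3.3, the most abundant family left out, full-length identical reads only, 1 mismatch allowed, and a minimum of 10 reads or none. Chosen after seeing the data were denominators without adapter fragments or without 24-nt, arthropod-type and partnered 21-nt reads, position 8 of the read ignored, and 5' starts up to 2 nt away. A 21-nt read was partnered when another 21-nt read of the library was its reverse complement over 19 nt with 2-nt 3' overhangs. A panel of 36 arthropod or widely shared animal miRNAs and 5 vertebrate ones was written after 4 of the arthropod ones had been noticed and before it was counted, and it was matched over the first 15 nt. The calculation was checked on simulated Poisson counts for heat against control over 22 families. Intervals covered the true ratio in 94.2% to 95.8% of draws. Families were called higher in 0% at a true ratio of 1, 0.114% at 1.5 and 100% at 3 and 4. Poisson error is what the intervals assume, and the draws held no spread between plants, PCR or sequencing error. They therefore give no rate of false calls for these libraries. Genome positions, a filter on genome matches and a filter on ribosomal, transfer and organelle RNA were not used here, and ribosomal fragments were found only by exact match to 5.8S and part of 18S. Figures were drawn with matplotlib 3.10.9.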

Results

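Small RNA was sequenced from leaves of Sorghum bicolor, a C4 cereal, to profile microRNAs (miRNAs) under drought, heat and both together. There were 4 libraries, 1 per condition. Control plants grew at 28 °C by day and 20 °C by night, with 14 h of light. Drought plants were kept at those temperatures and received no water for a week from day 73 after sowing. Heat plants were moved on day 30 to a separate chamber at 38 °C by day and 30 °C by night for 50 days. Combination plants grew in that heat and were also left without water from day 73. The libraries held 28338681 reads for control, 27427142 for drought, 31541978 for heat and 30238233 for the combination, in 8078241, 7289746, 5833870 and 5364997 distinct sequences. At this depth a count of 0 allows up to 0.106, 0.109, 0.0951 and 0.0992 RPM (reads scaled to a library of 1000000) in the same order. With 1 library per condition there is no spread between plants, no test was made and no difference has a replicate check. All intervals are 95% and, because PCR reads without molecular identifiers are not independent molecules, they and the floors cover counting error only.

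The 24-nt reads, the usual length of siRNAs that guide DNA methylation at repeats, made up a smaller share in both libraries from 38 °C. Their share of all reads was 36.2% in control (Wilson interval 36.15 to 36.19), 31.6% in drought (31.61 to 31.64), 16.2% in heat (16.23 to 16.25) and 16.4% in the combination (16.35 to 16.37). The 21-nt reads, the usual length of miRNAs, made up 30.2% in control (30.19 to 30.22), 33.8% in drought (33.80 to 33.83), 48.3% in heat (48.30 to 48.33) and 52.3% in the combination (52.33 to 52.36). The ratio of 24-nt to 21-nt reads was therefore 1.20, 0.935, 0.336 and 0.313 in that order. Among distinct sequences, each counted once, 24 nt made up 65.4%, 62.3%, 49.7% and 51.3%. Reads of the listed miRNA families were 5.66% of control, 5.01% of drought, 4.92% of heat and 5.13% of the combination, counted over 19 to 24 nt. With 1 mismatch allowed they were 5.91%, 5.24%, 5.59% and 5.40% in that order, so heat was no longer the lowest. Fragments of the 5' sequencing adapter made up 10.93%, 8.68%, 13.04% and 10.97% of reads, reads under 20 nt 8.97%, 7.73%, 11.3% and 8.43%, in the same order. Fragments of 5.8S ribosomal RNA made up 1.99%, 2.30%, 1.40% and 1.31%, while those of part of 18S ribosomal RNA made up 0.214%, 0.335%, 0.455% and 0.514%. Reads matching arthropod-type miRNAs were at 67.6 RPM in control, 112 RPM in drought, 2727 RPM in heat and 3804 RPM in the combination.

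**Figure D1:**
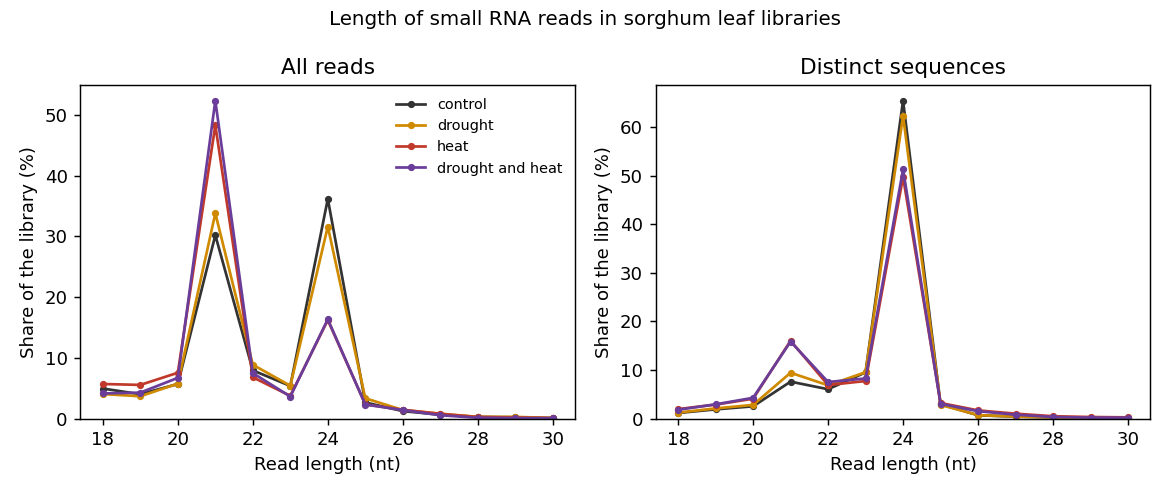
Share of reads (left, %) and of distinct sequences (right, %) by read length from 18 to 30 nt, with 1 line per library and no replicates. The 24-nt share of reads is 36.2% in control and 31.6% in drought but 16.2% in heat and 16.4% in the combination, where 21 nt is the main length at 48.3% and 52.3%.

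Drought at the lower temperature was compared with control to see which miRNAs differ after a week without water. Only 2 families passed 2-fold, both lower in drought. miR1432, a grass family predicted to target calcium-binding EF-hand proteins, was at 256 RPM in drought and 620 RPM in control, a ratio of 0.413 (0.401 to 0.424). miR529, which targets SPL transcription factors of phase change and panicle branching, had 80 reads in drought and 169 in control, a ratio of 0.489 (0.370 to 0.642). No family was at least 2-fold higher. Of 24 families with at least 100 reads over both libraries, 22 lay within 2-fold.

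By group, the growth transcription factor list had 5 of 6 members measured and none beyond 2-fold. In it miR166, which targets HD-ZIP III leaf polarity factors, had a ratio of 1.504 (1.490 to 1.517), or 1.314 (1.305 to 1.322) with shifted 5' starts counted. Also above 1 were miR171, which targets GRAS factors, at 1.42 (1.37 to 1.47) and miR159 at 1.06 (1.02 to 1.10). Below 1 were the NAC regulator miR164 at 0.705 (0.692 to 0.718) and miR396 at 0.796 (0.770 to 0.823). The list's median was 0.08 on the log2 scale, at percentile 94.6 of 10000 random lists of like abundance. The copper-responsive list had 3 of 4 members measured, with miR528 at 0.724 (0.687 to 0.763) and miR408 at 1.15 (0.979 to 1.35). Its median of -0.43, at percentile 13.3, is the value of miR397, at 0.740 (0.489 to 1.11). That value rests on 43 reads in drought and 60 in control from the listed 5' end. In control 96.7% of miR397 reads started elsewhere. In the phosphate and sulfate list, with a median of -0.45 at percentile 27.3, miR399 was at 0.625 (0.479 to 0.812) and miR827 at 0.862 (0.851 to 0.872). The most abundant families, miR172 and miR168, were at 0.798 (0.795 to 0.801) and 0.999 (0.995 to 1.003). miR156 was at 0.813 (0.806 to 0.820), on the same side of 1 as miR172. The miR168 value, with those of miR160 and miR394, changes side of 1 under other scalings. miR529 was not beyond 2-fold with TMM scaling, 1 mismatch allowed or shifted 5' starts, and miR1432 was not with full-length identical reads only. With reads of the miRNA families as the denominator, which moved the median family ratio by 0.18 on the log2 scale, the calls were 1 higher (miR530) and 1 lower (miR1432).

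Heat was compared with control to see which miRNAs differ after 50 days at the higher temperature. miR390, which starts production of the trans-acting siRNAs that repress auxin response factors, was highest relative to control among families with at least 100 reads over both libraries, at 18.1 RPM against 4.13 RPM, a ratio of 4.38 (3.58 to 5.39). miR437, a monocot family, had a ratio of 3.49 (2.91 to 4.20), and miR169, which targets NF-YA transcription factors, 2.22 (2.15 to 2.29). With 1 mismatch allowed the log2 ratio of miR437 was 1.12 in place of 1.80. With shifted 5' starts counted its ratio was 2.67 (2.30 to 3.11). Lower in heat were miR529, at 0.245 (0.173 to 0.341), and miR528, a monocot family that targets copper proteins, at 0.422 (0.398 to 0.448). Of 23 families measured, 18 lay within 2-fold, among them miR1432 at 0.502 (0.490 to 0.514).

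In the phase change and flowering list the juvenile-phase regulator miR156 had a ratio of 1.70 (1.69 to 1.71), while miR172, which represses AP2-type floral repressors and usually runs opposite to miR156, was at 0.742 (0.740 to 0.745). The list had 3 of 4 members measured, and its median of -0.43, at percentile 22.9, is the value of miR172. In the auxin list, with 4 of 5 members measured and 1 called, miR160 was at 1.53 (1.46 to 1.60) and miR167 at 0.729 (0.724 to 0.735). In the growth list, with none of 5 beyond 2-fold, miR396, which targets growth-regulating factors, was at 1.61 (1.57 to 1.66) and miR159 at 1.45 (1.393 to 1.501). The other conserved list, with miR169 called and miR394 at 1.87 (1.72 to 2.04), had a median of 0.91 at percentile 86.6. That median is the value of miR394, and the remaining member, miR530, was at 0.679 (0.480 to 0.956). In the phosphate and sulfate list, miR827 was at 0.634 (0.626 to 0.643) and miR399 at 0.784 (0.619 to 0.992). In the small RNA machinery list miR168, which targets the slicer AGO1, was at 0.808 (0.804 to 0.811). The calls were 3 higher and 2 lower, and 5 higher and 2 lower with reads of the miRNA families as the denominator, 3 and 3 with median-of-ratios factors and 4 and 2 with TMM, which moved the median by 0.20, -0.14 and 0.20. With full-length identical reads only, miR169 was not called. In the heat library a median of 6.16% of reads of abundant sequences carried a substitution at position 8, against 0.230% in control, and 0.608% one at position 18, against 0.0892%. Such reads were not assigned to a family, which lowers family counts in the heat library beyond what the intervals cover. With position 8 ignored, the log2 ratio of miR156 was 0.883 in place of 0.766. That of miR164 was 0.011 in place of -0.071.

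**Figure D2:**
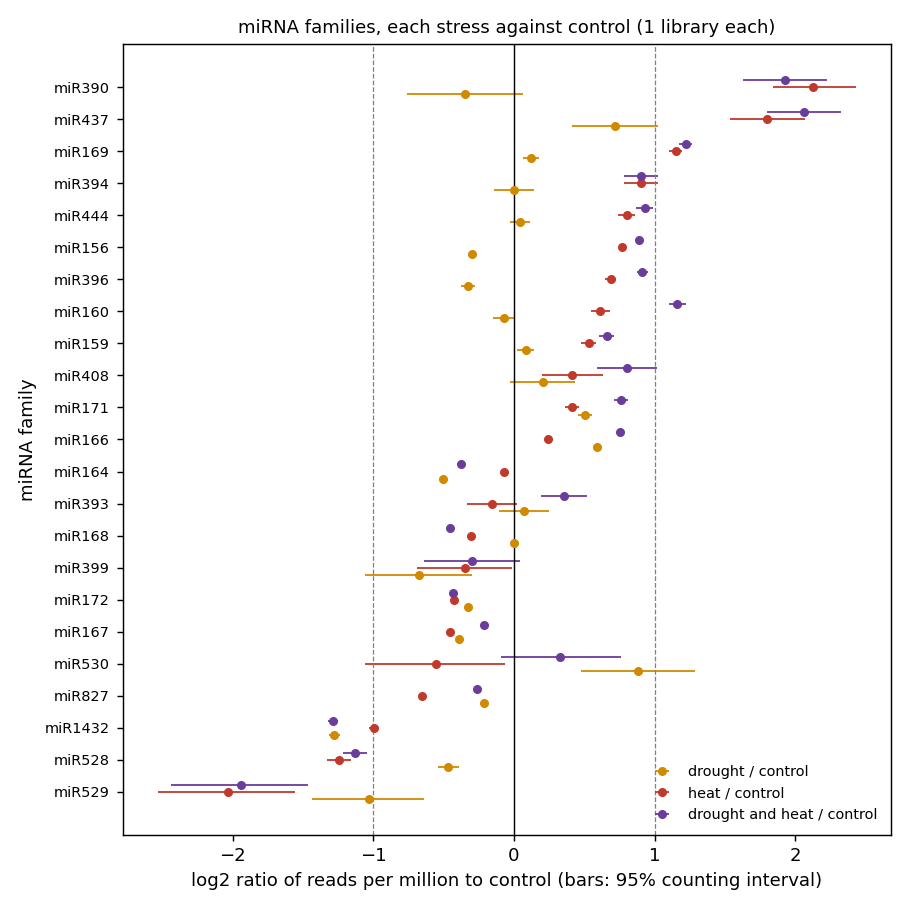
Log2 ratio of RPM to control for the families measured in all 3 stress libraries, with 1 library per condition and bars for the 95% counting interval, on a linear axis of log2 units with dashed lines at 2-fold. miR390 (4.38 in heat) and miR437 (3.49) lie furthest above control of the families shown and miR529 (0.245) furthest below; the values shown for miR160, miR168 and miR394 in drought, miR164 and miR393 in heat and miR393 and miR530 in the combination change side of 1 under other scalings.

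The combination was compared with control to see which miRNAs differ in the library from both stresses together. Of 23 families measured, those at least 2-fold higher were miR437 at 4.17 (3.49 to 5.02), miR390 at 3.797 (3.095 to 4.689), miR169 at 2.33 (2.26 to 2.41) and miR160, an auxin response factor regulator, at 2.24 (2.14 to 2.34). With 1 mismatch allowed the log2 ratio of miR437 was 1.28 in place of 2.06, below the 1.97 of miR390. With shifted 5' starts counted the ratios were 3.25 (2.81 to 3.77) for miR437 and 3.497 (2.884 to 4.264) for miR390. The families at least 2-fold lower were miR529 at 0.261 (0.184 to 0.362), miR1432 at 0.410 (0.399 to 0.421) and miR528 at 0.457 (0.430 to 0.484). Just within 2-fold were miR444, which targets MADS-box factors, at 1.90 (1.83 to 1.99), miR396 at 1.88 (1.83 to 1.93), miR394 at 1.87 (1.72 to 2.03) and miR156 at 1.85 (1.84 to 1.86). The 3 comparisons with control share 1 control library, so a chance value there enters all of them.

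The auxin list had 2 of 4 measured members called higher, and its median of 0.76 was at percentile 71.4. The phase change and flowering list had 3 of 4 members measured and a median of -0.44 at percentile 6.84. That median is the value of miR172, at 0.740 (0.737 to 0.742). The other measured members lay on opposite sides of 1, miR156 at 1.85 and miR529 at 0.261. In the monocot-specific list 1 of 4 members was called higher and 2 lower, and its median was -0.10 at percentile 15.8. Outside the calls, miR171 was at 1.70 (1.64 to 1.76), the copper-responsive miR408 at 1.74 (1.51 to 2.02) and miR168 at 0.729 (0.725 to 0.732). There miR166 was at 1.69 (1.67 to 1.70), but at 1.24 (1.23 to 1.25) with shifted 5' starts counted. The 7 calls, 4 higher and 3 lower, were 2 higher and 3 lower with median-of-ratios or TMM factors, where miR160 and miR169 were lost, and 8 higher and 2 lower with reads of the miRNA families as the denominator, where miR528 was lost. With full-length identical reads only, miR1432 was not called. Median-of-ratios factors, TMM and the miRNA denominator moved the median family ratio by -0.50, -0.41 and 0.14 on the log2 scale.

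Setting the combination against drought alone compares the hot and the cooler library of unwatered plants, which also differ in chamber. Of 23 families, 6 were at least 2-fold higher, namely miR390 at 4.83 (3.84 to 6.13), miR437 at 2.54 (2.18 to 2.96), miR396 at 2.36 (2.30 to 2.44), miR160 at 2.35 (2.25 to 2.46), miR156 at 2.28 (2.26 to 2.29) and miR169 at 2.15 (2.08 to 2.22). None was at least 2-fold lower, and miR528 was at 0.631 (0.592 to 0.672). With median-of-ratios or TMM factors, which moved the median by -0.53 and -0.48, the calls were 1 higher (miR390) and 3 lower (miR528, miR529 and miR530). The miR169 call was lost with full-length identical reads only and the miR437 call with 1 mismatch allowed. This comparison shares no library with heat against control. Of 23 families measured in both, 19 had ratios on the same side of 1, and miR169, miR390 and miR437 were at least 2-fold higher in both. With median-of-ratios factors the families called in both were instead miR390, higher, and miR528 and miR529, lower.

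Setting the combination against heat alone compares, at the higher temperature, the library from unwatered plants with that from heat alone. The position-8 substitutions in the heat library raise these ratios. None of 22 families reached 2-fold in either direction. The furthest were miR530 at 1.85 (1.34 to 2.57), on 110 and 62 reads, miR160 at 1.46 (1.41 to 1.52), miR166 at 1.43 (1.42 to 1.44) and the auxin receptor regulator miR393 at 1.43 (1.27 to 1.60), of which miR160, miR166 and miR393 change side of 1 with TMM factors. A scaling moves all families of a comparison by 1 factor, here by up to -0.61 on the log2 scale, and 17 of the 22 ratios lie close enough to 1 for their side of it to depend on that choice. Drought at the 2 temperatures had ratios on the same side of 1 for 15 of 22 families, and no family was at least 2-fold in both. The combination departed from the sum of the single-stress log2 ratios by more than 1 for 1 of 25 families, miR529, by 1.12 (0.42 to 1.82), and for none with median-of-ratios factors or reads of the miRNA families as the denominator.

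Several listed families were too rare to compare with the listed 5' ends. miR398, a copper-regulated family, had 29, 25, 29 and 41 reads in control, drought, heat and the combination, and miR319 had 4, 7, 35 and 35. The reproductive-tissue markers miR2118 and miR2275 had at most 2 reads in any library. The small RNA machinery list was measured through miR168 alone, since miR162 had at most 11 reads. miR393, miR395, miR397 and the trans-acting siRNA tasiARF were read mainly from a 5' end other than the listed one, so their listed counts (528 reads for miR393 in control) cover a minor part of each. The most abundant sequence of miR390 was AAGCTCAGGAGGGATAGCGCC, with 100, 78, 479 and 397 reads in control, drought, heat and the combination, that of miR1432 was CTCAGGAGAGATGACACCGA, with 15350, 6003, 8358 and 6537 reads, and that of miR528 was TGGAAGGGGCATGCAGAGGAG, with 3265, 2313, 1548 and 1608. Genome positions of these families were not analysed here.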

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

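The comparison with the vertebrate miRNAs was set before its result was seen; the other tests here were chosen after.

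Reads of arthropod-type miRNAs, outside the plant families compared, stood above their control level of 67.6 RPM in drought (112.334 RPM), heat (2726.84 RPM) and the combination (3803.96 RPM). The panel of 36 was written after 4 of its miRNAs had been noticed. Of the other 32, 9 had at least 10 reads in control, and 100% of these were at least 2-fold higher in heat (ratios 34.9 to 65.1). Much of the panel was nearly absent: only 20 of the 36 had at least 10 reads in heat and control together. Some, such as miR-277 and miR-281, had 0 reads in every library. Vertebrate-only miRNAs came to 0.00116% of the panel's level, which argues against RNA from handling. A candidate source is RNA of an arthropod on the leaves in the warm chamber, which the labels do not mention. The panel ratios compare levels only and cannot tell this source from another route into the libraries. How many other reads the source brought, and any effect on the plant's small RNAs, was not tested.

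In the heat library a median of 6.158% of reads of the 20 most abundant 21-nt sequences carried a substitution at position 8 (2.01% to 8.63%), against 0.230% in control, 0.178% in drought and 0.381% in the combination. Fragments of the synthetic 5' adapter, which no cell makes, carried it at 144.793% of the rate of those sequences, so a sequencing error at that cycle is a likely cause. A smaller excess stood at position 18, 0.608% in heat against 0.0892% in control, also in adapter fragments (0.943% against 0.214%), and no setting here allows for it alone. No biological explanation was tested. With position 8 ignored, heat against control had 6 calls in place of 5, the added one being miR394.

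In the main setting the drought ratio of 5 families lay on opposite sides of 1 at the 2 temperatures beyond counting error. The departures from additivity (log2) were 0.42 for miR156, 0.64 for miR167, 0.55 for miR396, 0.58 for miR528 and 0.61 for miR827. Over 25 families the median absolute departure was 0.42. Median-of-ratios factors moved the combination, drought and heat against control by -0.50, 0.03 and -0.14 (log2). TMM factors moved them by -0.41, 0.07 and 0.20. Either set of factors lowers every one of these departures, and the TMM shifts together would make all of them negative. The difference was not tested, since each condition has 1 library. TMM factors, which move all families of the combination against heat by -0.61 (log2), would place all 5 ratios at the higher temperature below 1. The position-8 substitutions lower counts in the heat library and so raise these ratios. With position 8 ignored, miR156 had log2 ratios to control of 0.883 in heat and 0.892 in the combination, in place of 0.766 and 0.889. This leaves the hot libraries nearly level for miR156. The log2 ratio of miR528 in heat was -1.16 in place of -1.24.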

How the results depend on the processing

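Denominators without adapter fragments or without 24-nt, arthropod-type and partnered 21-nt reads, position 8 ignored, shifted 5' starts and shares without adapter fragments or partnered reads were chosen after seeing the data; the other settings were fixed before. The count of 2 families in drought against control was 1 with TMM factors, with full-length identical reads, with 1 mismatch allowed and with shifted 5' starts. For the combination against heat, 0 became 1 without 24-nt, arthropod-type and partnered 21-nt reads in the denominator (miR530) and 1 with a minimum of 10 reads or none (miR162). The departure from additivity of miR529 was past 1 in the main setting, and 0 families were with reads of the miRNA families as the denominator or with median-of-ratios factors. The cause was not tested. The counts for heat against control (5) ranged from 4 to 7, the combination against control (7) from 5 to 10 and the combination against drought (6) from 4 to 8, but with median-of-ratios or TMM factors only miR390 was shared with the 6. miR319, with 4 control reads, was called in heat only with a minimum of 10 reads or none. Ratios of single named families were recomputed under 7 settings, which leave out TMM, a lower minimum and the denominators other than reads of 20 to 24 nt and of the miRNA families. In these no called ratio changed sign, and 124 of 140 called values stayed at 2-fold; over all named ratios 432 values stayed within the counting interval and 294 did not. Shares are given for control, drought, heat and the combination in that order. The 21-nt share was 7.61, 9.44, 16 and 15.9% among distinct sequences, 37, 40.6, 54.5 and 58.8% without sequences read once, 30.7, 34.5, 49.4 and 53% of 18 to 26 nt reads, 31.6, 35.4, 52.4 and 56.5% without adapter fragments and 25.2, 24.6, 34.3 and 35.5% without partnered 21-nt reads. The 24-nt share was 65.4, 62.3, 49.7 and 51.3% among distinct sequences, 27.9, 23.5, 9.98 and 10.2% without sequences read once, 36.8, 32.3, 16.6 and 16.6% of 18 to 26 nt reads, 39, 33.4, 17.4 and 17.1% without adapter fragments and 38.7, 36, 20.6 and 22.1% without partnered 21-nt reads. The 24-nt share stayed lower in both hot libraries than in control and drought under each of these settings. The miRNA share was 4.87, 4.39, 4.3 and 4.42% with full-length identical reads, 5.91, 5.24, 5.59 and 5.4% with 1 mismatch, 6.63, 5.86, 5.96 and 5.92% of 20 to 24 nt reads and 3.18, 3.02, 3.08 and 3.29% without the most abundant family. The filters on genome matches and on ribosomal, transfer and organelle RNA were not run, as no genome sequence was used here. Depth limits families with few reads, such as miR398 and miR162; no paired analysis was possible because each condition has 1 library.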

Other observations

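The tests of the 24-nt share, the counts with shifted 5' ends and the partnered reads were chosen after seeing the data; the counts of tags outside the families were fixed before.

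With 5' ends up to 2 nt from the listed ones counted, miR397, a copper-regulated family that targets laccases, was lower in both hot libraries. It was at 63.7 RPM in control, 42.4 RPM in drought, 27.5 RPM in heat and 23.1 RPM in the combination, ratios to control of 0.667 (0.619 to 0.718), 0.431 (0.397 to 0.468) and 0.362 (0.331 to 0.395). Its main read was TTGAGTGCAGCGTTGATGAGC, with 1644, 1048, 769 and 630 reads in the same order. miR393, read mainly as CTCCAAAGGGATCGCATTGAT (7960, 9707, 7510 and 10966 reads), had ratios of 1.23 (1.20 to 1.26), 0.846 (0.822 to 0.871) and 1.27 (1.24 to 1.31). The sulfate-responsive miR395, at 385, 332, 518 and 460 reads, had ratios of 0.891 (0.767 to 1.03), 1.21 (1.06 to 1.38) and 1.12 (0.976 to 1.29). tasiARF, made downstream of miR390, had 185, 134, 228 and 207 reads and ratios of 0.748 (0.595 to 0.940), 1.11 (0.908 to 1.35) and 1.05 (0.856 to 1.29), beside 4.06 (3.36 to 4.94) and 3.497 (2.884 to 4.264) for miR390 in heat and the combination, counted the same way. In miR166, 49.7%, 42.4%, 35.6% and 31.7% of reads in control, drought, heat and the combination started at such other ends, and with them its ratio in heat was 0.922 (0.916 to 0.928) in place of 1.18.

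Many 21-nt reads had an opposite-strand partner with the 2-nt overhang left by Dicer-like enzymes. They made up 6.64% of all reads in control, 12.3% in drought, 21.3% in heat and 26.1% in the combination, while 21-nt reads without a partner made up 23.6%, 21.5%, 27.03% and 26.3%. With each library thinned to about the 8560226 21-nt reads of control, the partnered part was 21.98%, 35.7%, 39.7% and 46.1% of them. Whether they come from sorghum repeats, a virus or another organism was not analysed here. Among tags of 20 to 24 nt outside the families with at least 500 reads over both libraries, 3115 of 5732 were at least 2-fold higher in heat than in control, of which 2959 were 21 nt, and 418 were lower, of which 227 were 24 nt. The lengths of all 5732 tags are not given here, so this split may only follow the library-wide shift to 21 nt. The 3115 include 137 position-8 variants, each 1 substitution from a family sequence or from a tag at least 10 times as abundant, among them the 3 with the highest lower bounds of the ratio, and 23 tags that match the animal panel. In drought 733 of 4504 were higher and 79 lower, and in the combination 3602 of 5972 and 377, with 6 position-8 variants and 37 panel tags among the 3602.

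Among distinct sequences the 24-nt share in heat minus control was -15.6989 percentage points, which argues against displacement by a few abundant 21-nt sequences as the cause of the lower 24-nt share. Among reads other than 21 nt it was -20.4052 points, which argues against more 21-nt reads alone, and among reads of 20, 22, 23 and 24 nt without adapter it was -16.8551 points, which argues against adapter fragments. Fragments of broken RNA stay open: reads of 5.8S and part of 18S together were -0.348 points in heat minus control, but the 18S part alone was 0.455% against 0.214%, and other ribosomal or transfer RNA was not analysed here. A lower output of 24-nt siRNAs at 38 °C may account for the lower share, as a hypothesis not tested here. Reads of other organisms outside 21 nt, the separate chamber and plant-to-plant differences also stay open, since temperature and chamber go together and each condition has 1 library.

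The 2 most abundant 21-nt tags outside the listed families, named after their values were seen, were TGGGAAGCAATTCGTCGAACA, with 1171686 reads in control, 822765 in drought, 806773 in heat and 988344 in the combination, and TGGGGAAGCAATTCGTCGAAC, with 718893, 758214, 835984 and 1107851.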
